A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

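RNA of Saccharomyces cerevisiae strains was compared on 30 two-channel arrays, each holding a test strain and a reference strain, or 1 reference strain in both channels. Per the labels' protocols, cells were grown in CSM-Trp-His medium at 26 °C to an OD600 of about 0.8 and shifted to 37 °C for 45 min, except in the YJS8 group kept at 26 °C. Per the labels' protocols, the arrays were scanned with a GenePix 4000A scanner and read with GenePix Pro 4.0. The deposited values are log2 ratios of the 2 channels, 1 per spot and array, made by the authors. They carry a constant of 3e-07, and the normalization behind them is not given in the sources used here. Strains are named as the labels give them, and their genotypes are not given there, so none was assumed. The labels do not say whether arrays of 1 strain come from separate cultures, so the p-values measure the spread between arrays.

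The array holds 6400 spots, of which 5955 to 6388 had a value on each array. Of these spots, 5578 carried 1 gene, 0 carried several and 822 carried none. Systematic names were matched to the supplied gene table for 5573 spots, and 5 kept the name of the platform. Spots of the same gene were averaged, which gave 5547 genes, of which 5519 were tested in at least 1 group.

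The columns of YKH100 replicate 2 and YJS8 replicate 2 held identical values, and the labels do not decide to which strain they belong. Both were left out of the main model, which therefore used 21 arrays where the design had 23, and left 1 array each for YKH100 and YJS8. This departure and the alternatives for it were chosen after seeing the data. The values of opposite channel orientations of 1 strain correlated positively in 8 of the 9 groups without the repeated column, so they were read as already turned by the authors, and the dye effect was fitted as its own term.

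The labels do not say whether the ratio is test over reference. A rule written before the data were examined called the direction likely only if TFIID, SAGA and TBP regulators with an absolute log2 above 2 all had 1 sign. That rule left the direction open, because GCN5 and SPT3 had negative values in some strains while GCN5 and BDF1 had positive values in others. The direction was then read from the size of the values, after seeing the data. On the 3 YKH105 self arrays SPT3 stayed between 0.0495 and 0.164 around the array median. On the 4 YJS6 self arrays GCN5 stayed between -0.123 and 0.245. A self ratio shows neither the level of a transcript nor the direction, so the reading that follows remains an assumption. Values of -8.33 for SPT3 in YKH104 and -5.40 for GCN5 in YKH101 were read as a lower level in the test strain, and all ratios as likely test over reference.

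A second rule written before the data were examined kept the deposited scale only if the medians of all 7 self arrays lay within 0.2 of 0. They ran from -0.545 to 0.671 and 4 lay beyond 0.2, so each array was centred on its median. A change is therefore relative to the median gene of the array, and the deposited scale is an alternative.

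A linear model was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes), with 1 term per strain and temperature group and 1 gene-wise dye term. A gene was tested in a group if it had a value in both orientations of that group, or on its 1 array for YKH100 and YJS8, and on at least 18 arrays. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a group were called higher or lower. The fit left 9 residual degrees of freedom and a prior of 2.87. The number of arrays limits the precision, and the median standard error was 0.145 for 3 arrays, 0.173 for 2 arrays and 0.251 for 1 array. All groups shared 1 estimate of spread per gene, which need not match the spread between the arrays of each group. A group with 1 array was assumed to vary like the others. Contrasts of the same fit compared YJS8 at 37 °C with YJS8 at 26 °C and all 20 pairs of shifted strains with a common reference. No paired analysis was possible because replicate 1 always had the test strain in channel 1 and replicates 2 and 3 in channel 2, so that pairing by replicate number cannot be separated from the dye term already fitted, and the labels do not say what the array numbers in the titles stand for. Among the test arrays against YKH105, those with the test strain in channel 1 had low array numbers and those in channel 2 high ones, so there the dye effect cannot be separated from an effect of the array series.

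Of 29 gene lists fixed before the data were examined, 28 had members on the array, and the list of the mitochondrial genome had none. They were tested with camera of limma (cameraPR) on the model's statistics with the preset correlation of 0.01, adjusted over the 307 list and group tests with at least 5 members, and again with an estimated correlation. The lists of the YJS8 temperature contrast, tested with both correlations, were adjusted over the 28 lists of that contrast.

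Genes were named by a rule written before the data were examined. It took, per group, the 5 highest and 5 lowest called genes with the same sign on every array, up to 3 called members of each list that passed camera, and any TFIID, SAGA or TBP regulator with an absolute log2 above 2 on every array. Genes named outside this rule are marked as chosen after their values were seen.

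The 7 self arrays gave the background, and their pairs were tested with the spread of the test arrays. A self array may hold 1 RNA in both channels, so this background need not cover differences between cultures. The design had taken the halved difference of 2 self arrays as if both had been read in 1 orientation, but the sign of each self array's dye effect had to be read from the data, so pairs with opposite dye signs were averaged instead. This was decided after seeing the data.

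The steps were tested on simulated data with 200 genes changed by a known amount. In a simulation of YKH101 with 5493 genes, 74% of the genes changed by a log2 of 1 were called, 99.5% of those changed by 2 and 0.5% of those changed by 0.5. In a simulation of YJS8 with 5489 genes and 1 array, these shares were 44%, 89% and 1%. In a simulation of YKH109 with 5491 genes and 3 arrays, they were 86%, 97.5% and 23%. Unchanged genes called by mistake numbered 0 to 7 in YKH101, 0 to 6 in YJS8 and 5 to 15 in YKH109. The noise was drawn independently for each gene and array, and fewer genes were changed than were called in most groups. These shares therefore need not hold for the real arrays.

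Alternatives covered the scale, the dye term, the arrays in the fit, missing values, the moderation of variances and a 1.5-fold minimum. They also covered centring in blocks of spots, spots with ratios of small whole numbers, genes that did not follow the array median, the repeated column, and leaving out each array. The planned test of an upstream TATA element was not run, since no genome sequence was used here.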

Results

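The arrays measured transcript levels in yeast strains whose series title names TFIID and SAGA, the coactivator complexes that bring the TATA-binding protein (TBP) to promoters. The question named by the title is how genes across the genome depend on these complexes. On 16 arrays the reference strain was YJS6 and on 14 it was YKH105. Groups YKH100, YKH101, YJS7, YJS8 and YJS9 were shifted to 37 °C and compared with YJS6, as was YJS8 kept at 26 °C, with 2 arrays each. Groups YKH104, YKH106, YKH107 and YKH108 had 2 arrays each against YKH105, and YKH109 had 3. A further 7 self arrays held 1 reference strain in both channels. The arrays carried values for 5955 to 6388 of 6400 spots, and their number limits the precision. Replicate 2 of YKH100 and replicate 2 of YJS8 held the same values and were left out, so these strains rest on 1 array each at 37 °C and have no replicate check of their own.

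Values are log2 ratios read as likely test over reference, a direction that the labels do not give, and are stated relative to the median gene of each array. That median itself moved. The mean of the array medians over both orientations was -0.69 in YKH101, -0.51 in YJS9, -0.96 in YKH107, -0.69 in YKH108 and -0.96 in YKH109. It was -0.26 in YJS8 at 26 °C, 0.19 in YJS7, 0.11 in YKH104 and 0.17 in YKH106. The single arrays of YKH100 and YJS8 had medians of -0.34 and -0.97. In pairs of self arrays this mean ran from -0.21 to 0.38. Errors are standard errors (SE) from limma, adjusted p-values are from limma or its camera test, and n is the number of arrays.

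The genes of TFIID, SAGA and the TBP regulators were looked at first. GCN5 (YGR252W), the histone acetyltransferase of SAGA, was lower by a log2 of -4.97 ± 0.27 (SE, n = 1) in YKH100 and -5.40 ± 0.19 (SE, n = 2) in YKH101. It was higher in YJS7 (2.48 ± 0.19, SE, n = 2) and YJS9 (3.21 ± 0.19, SE, n = 2). SPT3 (YDR392W), a SAGA subunit that contacts TBP, was lower in YKH104, with arrays at -8.1 and -8.57, and in YKH107, with arrays at -7.5 and -8.96. Values this low depend on the background of the test channel, which was not used here, so their size is no exact measure. In values chosen after they were seen, SPT3 was higher in YKH108 (1.43 ± 0.29, SE, n = 2) and was at -1.06 in YKH106, where it did not pass. BDF1, a bromodomain protein that binds TFIID, was higher in YJS9 by 2.39 ± 0.19 (SE, n = 2). On the self arrays GCN5 with YJS6 ranged from -0.12 to 0.24 around the array median and SPT3 with YKH105 from 0.05 to 0.16. As the genotypes are not given, these values check no label.

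**Figure D1:**
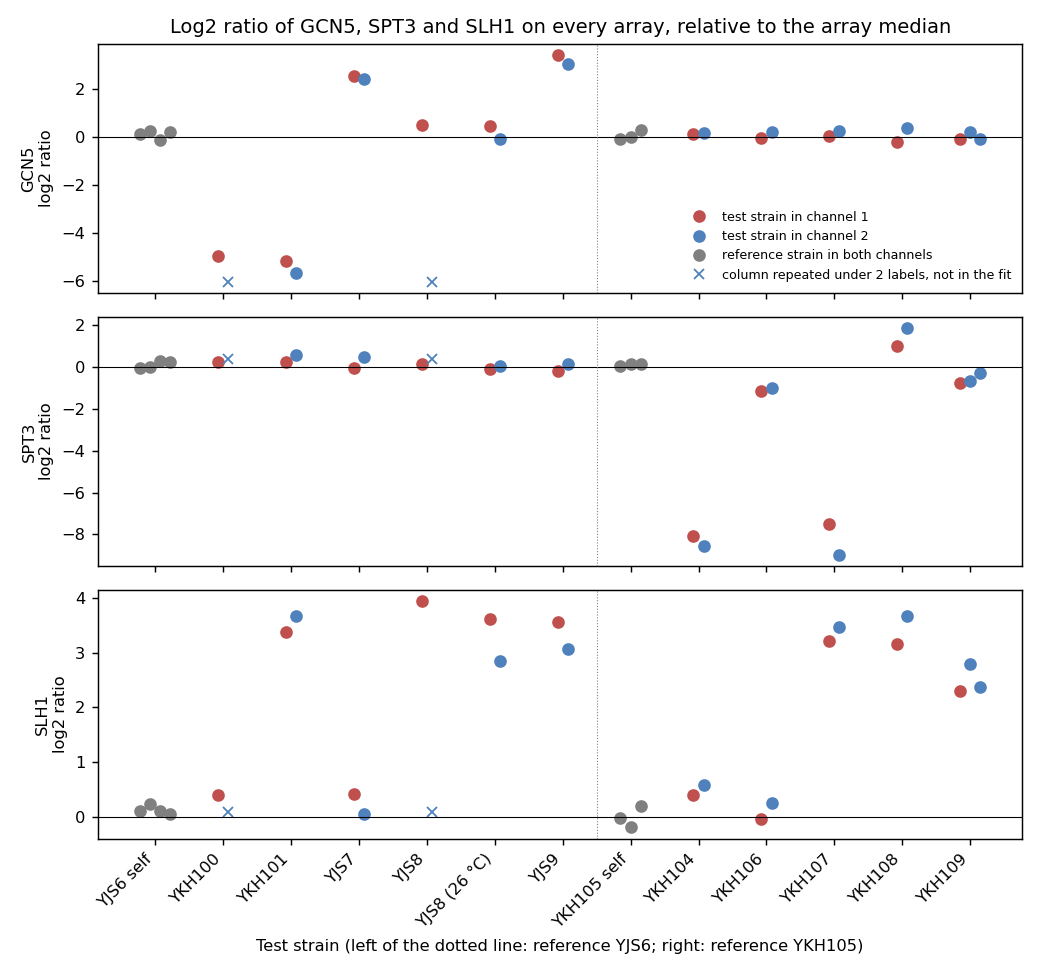
Log2 ratio of GCN5, SPT3 and SLH1 relative to the array median (y axes) by test strain (x axis), with 1 point per array coloured by the channel of the test strain, grey for self arrays and a cross for the repeated column. GCN5 is at -5.13 and -5.66 on the arrays of YKH101, and SPT3 is at -8.1 and -8.57 on those of YKH104.

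Strains differed widely in the number of genes that changed. YKH109 had 2901 of 5491 tested genes past the limma threshold, YKH107 had 2662, YJS9 2388, YKH101 2158 and YKH108 2033. YJS8 at 37 °C had 872, YJS7 774, YKH104 746, YKH100 73 and YKH106 60. YJS8 at 26 °C had 1, in a group whose effects varied less than the shared spread allowed for. Among 9 pairs of self arrays, where no strain differed, the same threshold called 1 to 26 genes. Each pair combined 2 arrays, so this background matches the groups with 2 arrays. It does not match YKH100 and YJS8 at 37 °C, with 1 array each, or YKH109 with 3. Counts of groups with unlike numbers of arrays cannot be ranked, because power differs. These pairs may hold 1 RNA in both channels, so their counts set no bound on differences between cultures. Because of the shift of the array medians, the balance of higher and lower genes depended on the scale, and both splits are given for each strain. Of the 26 heat shock genes, 18 did not follow the array median on the self arrays, which was true of 432 of 5519 tested genes, so centring can raise or lower the values of this list.

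**Figure D2:**
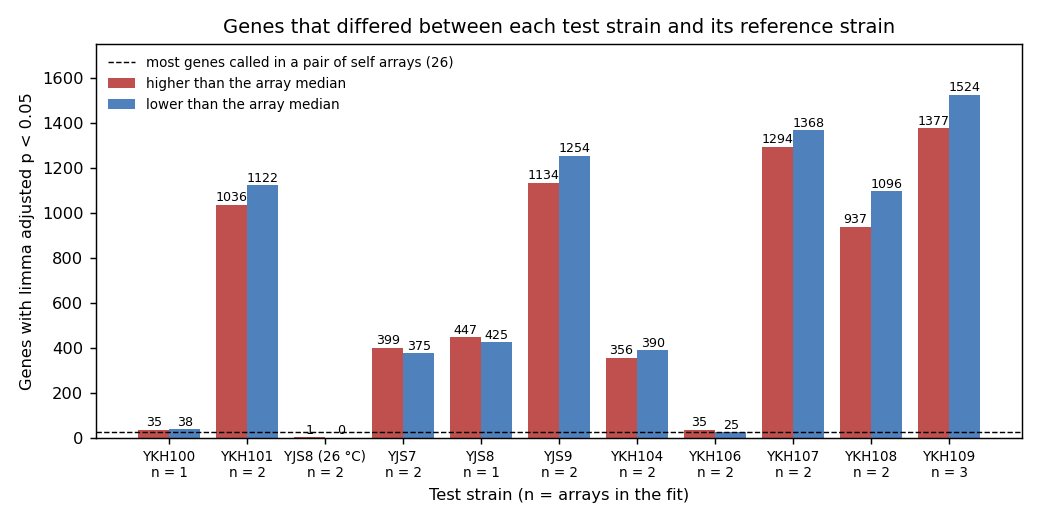
Number of genes (y axis) that were higher or lower than the array median in each test strain (x axis; limma, adjusted p under 0.05), with a dashed line at 26, the most genes called in a pair of self arrays. Bars for YKH109 reach 1377 higher and 1524 lower genes, and as deposited, which is not drawn, they would be 112 and 3329.

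YJS8 was the strain measured at both temperatures, which asks what the shift to 37 °C adds. At 26 °C SLH1 (YGR271W), an RNA helicase gene, was higher by a log2 of 3.23 ± 0.21 (SE, n = 2; adjusted p = 1.79e-05) and no other gene passed. The effects in this group had a standard deviation of 0.133, below their median SE of 0.173, which came from a spread shared by all groups. By limma 38 of 5492 genes had an unadjusted p under 0.05. The test was therefore strict here, and genes without a call were not shown to be equal in YJS8 and YJS6. With the repeated column under both strains or as YJS8 alone, SLH1 stayed at 3.23 and did not pass (limma adjusted p = 0.0745 and 0.147). Those settings add a YJS8 array with SLH1 at 0.08, where the other YJS8 arrays ran from 2.85 to 3.94. With the column as YKH100 alone SLH1 was at 3.23 and passed (limma adjusted p = 5.11e-06). Without replicate 2 at 26 °C it was at 3.68. At 37 °C SLH1 was at 3.95 ± 0.30 (SE, n = 1), MF(ALPHA)2, an alpha pheromone gene, was lower (-2.19 ± 0.49, SE, n = 1), and CIT2, the peroxisomal citrate synthase, rose by 3.02 ± 0.24 (SE, n = 1). General stress genes rose with a median of 1.68 (23 of 35 higher, 28 adjusted over the list alone), among them TSL1, a trehalose synthase subunit (2.75), and ALD3, an aldehyde dehydrogenase (2.59). Tricarboxylic acid (TCA) cycle genes rose with a median of 1.18 (9 of 15 higher, 10 adjusted over the list alone), including ACO1, the aconitase (2.25), and IDH2, an isocitrate dehydrogenase subunit (2.14). Ribosomal protein genes fell with a median of -0.80 (66 of 134 lower and 2 higher, 83 and 2 adjusted over the list alone).

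Glycolysis and fermentation genes in YJS8 at 37 °C had a median of 1.14 (13 of 17 higher, 16 adjusted over the list alone; adjusted p = 2.2e-07, or adjusted p = 0.0648 with an estimated correlation). PFK2, a phosphofructokinase subunit, was at 1.48 and ADH1, the main fermentative alcohol dehydrogenase, at 1.34. Sulfur and methionine genes rose (median 0.46, 8 of 22 higher, 9 adjusted over the list alone), led by STR3, a cystathionine beta-lyase (1.97), and MUP1, a methionine permease (1.67), although the list median was -0.52 on the deposited scale. The 8 selection marker genes had a median of 1.09 with 5 higher (5 adjusted over the list alone), among them ADE2 of purine synthesis (1.94) and CAN1, the arginine permease (1.56). TBP regulators had a median of 0.47 (5 of 12 higher, 6 higher and 1 lower adjusted over the list alone; adjusted p = 0.246 with an estimated correlation), with BDF2 at 1.58 and BUR6, a subunit of the NC2 repressor of TBP, at 1.41, and the list median was -0.50 on the deposited scale. Heat shock proteins (0.75, adjusted p = 0.219 with an estimated correlation) and proteasome genes (0.54, adjusted p = 0.175 with an estimated correlation) had positive medians after centring that were below 0 as deposited. The proteasome list had 12 of 36 higher (14 adjusted over the list alone), and the heat shock list 8 of 26 (10 adjusted over the list alone), HSP26 and SSA4 among them at 2.88 and 2.32. Ribosome biogenesis genes (median -0.30), amino acid biosynthesis (0.38), mating (0.46) and respiration genes (0.19) passed with the preset correlation, with adjusted p = 0.384, 0.49, 0.438 and 0.548 with an estimated correlation, and the last 3 had medians below 0 on the deposited scale.

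Other genes with large values in YJS8 at 37 °C rest on its 1 array. ATG11, an autophagy adaptor, was at 4.45, MRX18 at 4.00, NOP56, a nucleolar protein of ribosome synthesis, at 3.81 and YOR342C at 3.62. URA4, the dihydroorotase of pyrimidine synthesis, was at -6.62, PEX7, a peroxisomal import receptor, at -3.26, RPS11A of the small ribosomal subunit at -3.25 and GRS2, a glycyl-tRNA synthetase, at -2.30. In all, 447 genes were higher and 425 lower, and on the deposited scale 8 were higher and 115 lower. With the repeated column under both strains 213 were higher and 256 lower, and with it as YJS8 alone 175 and 189.

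The contrast of YJS8 at 37 °C minus YJS8 at 26 °C, each against YJS6 treated alike, had 239 genes with a higher and 174 with a lower strain effect at 37 °C. With the repeated column kept under both strains there were 12 (7 higher and 5 lower), and with it as YJS8 alone 7. Read as YKH100 alone, the column left the number of genes within 1.5 times that reported. SIP18, a desiccation-response gene, differed by 3.61 ± 0.52 (SE), DUR3, a urea and polyamine transporter, by 3.18 ± 0.67 (SE), TRK2, a potassium transporter, by 3.35 ± 0.53 (SE), MRX18 by 4.43 and YOR342C by 3.15. PHO3, an acid phosphatase, differed by -2.30 ± 0.25 (SE), MF(ALPHA)2 by -2.19 ± 0.60 (SE), PEX7 by -3.50, RPS11A by -3.24 and GRS2 by -2.14. General stress genes had a median difference of 1.67 (camera adjusted p = 2.32e-26, or adjusted p = 2.43e-07 with an estimated correlation) and TCA cycle genes of 0.83 (adjusted p = 1.36e-10, or adjusted p = 2.33e-10 with an estimated correlation). Ribosomal protein genes had -0.88 (adjusted p = 4.59e-25, or adjusted p = 0.00994 with an estimated correlation). With 1 array at 26 °C left out, DUR3 (3.28 and 3.10) and MF(ALPHA)2 (-2.46 and -1.97) kept their size but did not pass, nor did PEX7 (-3.15) and GRS2 (-1.60) without replicate 1. The contrast set 1 shifted array against 2 unshifted arrays. On the deposited scale limma called 0 genes, with 482 at an unadjusted p under 0.05, and with YJS8 at 26 °C replicate 2 left out it called 153.

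YKH100 had low GCN5 and 73 changed genes on its 1 array. With the repeated column read as YKH100 there were 318, and with it under both strains 197. SPG4, a stationary-phase gene, was higher by a log2 of 2.09 ± 0.37 (SE, n = 1), CHA1, the serine and threonine deaminase, by 2.31 ± 0.25 (SE, n = 1), UBX4, a Cdc48 cofactor, by 2.51 ± 0.19 (SE, n = 1), PDH1 by 2.08 and YDR248C by 2.97. The SAGA list (median 0.07, mean -0.35, 1 of 15 lower, 1 adjusted over the list alone) tested as down (adjusted p = 0.0394, or adjusted p = 0.241 with an estimated correlation) with GCN5 as its 1 lower member, and its median was -0.31 on the deposited scale. Histone genes had a median of -0.53 with 1 of 10 lower (4 adjusted over the list alone; adjusted p = 0.052 with an estimated correlation), HHO1, the linker histone, at -0.94. General stress genes had a median of 0.48 (0.07 on the deposited scale) with 2 higher, GSY2, a glycogen synthase (1.56), and RTN2, a reticulon (1.14), and with 1 lower, GPD1 of glycerol synthesis (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.215 with an estimated correlation). Ribosomal protein genes had a median of -0.23 with 2 of 135 lower (2 adjusted over the list alone; adjusted p = 0.375 with an estimated correlation). Mating genes had a median of -0.14 with 2 of 29 lower, FIG1 (-1.69), of mating projections, and STE3 (-1.09), the a-factor receptor (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.299 with an estimated correlation). Camera with the preset correlation also passed G1 and S phase genes (median -0.36, adjusted p = 0.241 with an estimated correlation) and ergosterol genes (-0.17, adjusted p = 0.444 with an estimated correlation). It passed sulfur (0.20), proteasome (0.30) and mitochondrial ribosome genes (0.23) too, whose medians were below 0 on the deposited scale and whose adjusted p-values were 0.246, 0.363 and 0.223 with an estimated correlation.

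Further values in YKH100 rest on its 1 array. YPC1, a ceramidase gene, was at -6.12, ENP1, an 18S rRNA processing factor, at -5.15, YAR061W at -4.14, ZEO1 at -3.62 and RPS14A of the small ribosomal subunit at -3.16. In the repeated column, if read as YKH100, YAR061W turned to 0.98 in the combined estimate and YPC1 and ENP1 no longer passed. YKH100 had 35 genes higher and 38 lower, and on the deposited scale 1 higher and 10 lower.

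YJS7, in which GCN5 was higher, had lower histone and higher stress gene transcripts. Histone genes fell with a median of -0.68 (7 of 10 lower, 8 adjusted over the list alone), among them HTA2 (-1.02 ± 0.17, SE, n = 2) and HHF1 (-0.96 ± 0.16, SE, n = 2), which encode histones H2A and H4. General stress genes rose with a median of 0.81 (18 of 36 higher and 1 lower, 23 and 1 adjusted over the list alone), including CTT1, the cytosolic catalase (1.76), and DDR2, a stress-responsive gene (1.70). Without replicate 2, DDR2 was at 1.08 and HTA2 at -0.86, and neither passed. Mitochondrial ribosome genes rose with a median of 0.38 (13 of 55 higher, 22 adjusted over the list alone), MRP20 at 0.90, which did not pass without replicate 2 (0.66). Ribosomal protein genes had a median of -0.46 (37 of 133 lower and 1 higher, 65 and 1 adjusted over the list alone; adjusted p = 0.0852 with an estimated correlation), with RPS9A at -1.23, and at -0.79 without replicate 1, where it did not pass.

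SPG4, a stationary-phase gene, was higher in YJS7 by 2.67 ± 0.25 (SE, n = 2) and PDH1 by 2.01 ± 0.17 (SE, n = 2). SPG1, at 2.14, rested on arrays at 3.33 and 0.95, and was at 0.98 without replicate 1, where it did not pass. YNL040W was lower by -2.99 ± 0.14 (SE, n = 2) and YDR222W by -2.22 ± 0.20 (SE, n = 2). RRP12, a ribosome export factor (-1.56 and -4.19 on the 2 arrays), CCW22 (-0.93 and -4.06) and TOF1, a replication checkpoint mediator (-4.77 and -0.07), were lower with arrays far apart, and TOF1 was at -0.14 with replicate 1 left out and CCW22 at -0.97 with replicate 2 left out, where they no longer passed. Ergosterol genes (median -0.22, 5 of 22 lower, 1 higher and 8 lower adjusted over the list alone; adjusted p = 0.311 with an estimated correlation) included ERG4 at -1.17. Iron genes (median 0.33, 5 of 21 higher, 6 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation) included FIT2, a cell wall mannoprotein of siderophore uptake, at 1.48, and at 0.83 without replicate 2, where it did not pass. Amino acid biosynthesis (median -0.28), mating (-0.36), G1 and S phase (-0.31) and seripauperin genes (0.27) passed with the preset correlation, with adjusted p = 0.373, 0.246, 0.319 and 0.548 with an estimated correlation. Amino acid biosynthesis and ergosterol genes had medians of -0.09 and -0.04 on the deposited scale. Without replicate 1 camera turned the direction of the seripauperin list (adjusted p = 0.975). FIG1 (-2.12 ± 0.19, SE, n = 2) was the lowest mating gene. In YJS7, 399 genes were higher and 375 lower, and 19 and 6 on the deposited scale. With 1 array left out, the number of genes fell to 510 without replicate 1 and 330 without replicate 2.

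YKH101 combined low GCN5 with higher general stress and lower ribosomal protein genes. MEP2, the high-affinity ammonium permease, rose by a log2 of 3.90 ± 0.21 (SE, n = 2), PUT1, the proline oxidase, by 3.75 ± 0.28 (SE, n = 2) and DAL80, a repressor of nitrogen catabolic genes, by 3.70 ± 0.57 (SE, n = 2). SSA3, an Hsp70 gene, rose by 3.85 ± 0.24 (SE, n = 2) and AGA2, the binding subunit of a-agglutinin, by 3.55 ± 0.23 (SE, n = 2). Besides GCN5, YNL040W was lower by -3.42, FAA4, a long-chain acyl-CoA synthetase, by -2.96, RNH203, an RNase H2 subunit, by -2.74 and LDO45, a lipid droplet protein, by -2.67. General stress genes rose with a median of 1.66 (30 of 35 higher, 30 adjusted over the list alone), such as DDR2 (3.46) and TSL1 (3.06).

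Ribosomal protein genes in YKH101 fell with a median of -1.04 (115 of 134 lower, 121 adjusted over the list alone), RPL23A at -2.01 ± 0.23 (SE, n = 2). TCA cycle genes rose with a median of 0.97 (10 of 15 higher, 10 adjusted over the list alone), CIT1, the mitochondrial citrate synthase, at 2.40 ± 0.15 (SE, n = 2). Glycolysis and fermentation genes had a median of 0.96 (14 of 17 higher and 1 lower, 16 and 1 adjusted over the list alone; adjusted p = 0.175 with an estimated correlation), with PDC5 and PDC1, pyruvate decarboxylases, at 1.73 and 1.33. Genes of G1 and S phase had a median of -0.67 (13 of 27 lower, 14 adjusted over the list alone; adjusted p = 0.216 with an estimated correlation), including POL1, the catalytic subunit of DNA polymerase alpha (-1.99), and CDC21, the thymidylate synthase (-1.52). Mating genes had a median of 0.61 (15 of 29 higher and 6 lower, 15 and 6 adjusted over the list alone; adjusted p = 0.241 with an estimated correlation), with STE2, the alpha-factor receptor, at 3.06, and a list median of -0.08 on the deposited scale. Proteasome genes (0.60, 21 of 36 higher, 23 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation) and mitochondrial ribosome genes (0.38, 18 of 55 higher and 1 lower, 18 and 1 adjusted over the list alone; adjusted p = 0.246 with an estimated correlation) had medians of -0.09 and -0.31 on the deposited scale. Heat shock proteins (median 0.96, 16 of 26 higher, 16 adjusted over the list alone) passed with the preset correlation, with adjusted p = 0.134 with an estimated correlation. So did TBP regulators (0.25, with BDF1 at 1.87) and sulfur genes (0.36, with MUP1 at 2.11), at adjusted p = 0.31 and 0.115 with an estimated correlation, and both had medians below 0 on the deposited scale. In YKH101, 1036 genes were higher and 1122 lower, and 117 and 1709 on the deposited scale. Without replicate 1 there were 1254 genes and without replicate 2 there were 1162.

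YJS9 shared the higher GCN5 signal with YJS7 and changed iron and sulfur genes. Iron genes rose with a median of 1.29 (14 of 21 higher, 14 adjusted over the list alone), led by TIS11, an mRNA-binding protein of iron limitation (3.51 ± 0.63, SE, n = 2), and FIT2 (3.04 ± 0.34, SE, n = 2). Sulfur and methionine genes rose with a median of 0.90 (16 of 22 higher and 3 lower, 16 and 3 adjusted over the list alone), STR3 at 2.36 ± 0.21 (SE, n = 2). PUT1 rose by 4.44 ± 0.28 (SE, n = 2), CIS1 by 4.14 ± 0.19 (SE, n = 2), AGA2 by 4.03 ± 0.23 (SE, n = 2) and CHA1 by 3.84 ± 0.17 (SE, n = 2). The alpha pheromone genes MF(ALPHA)1 and MF(ALPHA)2 were lower by -3.45 and -3.34, YNL040W by -3.18, FAA4 by -3.16 and OLE1, the fatty acid desaturase, by -2.80. The mating list as a whole did not pass camera in YJS9 (median 0.62, 14 of 27 higher and 6 lower, 14 and 6 adjusted over the list alone; adjusted p = 0.0761, or adjusted p = 0.475 with an estimated correlation).

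TCA cycle genes in YJS9 rose with a median of 1.06 (9 of 15 higher and 2 lower, 10 and 4 adjusted over the list alone), CIT2 at 2.53 ± 0.17 (SE, n = 2). Ribosomal protein genes had a median of -0.83 (91 of 134 lower and 3 higher, 94 and 3 adjusted over the list alone; adjusted p = 0.175 with an estimated correlation), RPL23A at -1.68. General stress genes had a median of 0.78 (20 of 34 higher and 1 lower, 21 and 2 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation), GSY2 at 3.15. Ergosterol genes had a median of 0.59 (12 of 22 higher and 4 lower, 13 and 4 adjusted over the list alone; adjusted p = 0.297 with an estimated correlation), with ERG25, a sterol methyl oxidase, at 1.85 and ERG3, a sterol desaturase, at 1.76. Seripauperin genes, a subtelomeric family, had a median of 0.59 (13 of 24 higher, 14 adjusted over the list alone; adjusted p = 0.47 with an estimated correlation). Ergosterol and seripauperin genes had medians of 0.08 and 0.08 on the deposited scale, and glycolysis genes of 0.05. Genes of G1 and S phase (-0.63, 15 of 26 lower, 15 adjusted over the list alone) and glycolysis genes (0.56, 8 of 17 higher, 10 adjusted over the list alone) had adjusted p = 0.175 and 0.311 with an estimated correlation. Heat shock proteins (0.46) and cell wall genes (0.47) passed with the preset correlation, at adjusted p = 0.375 and 0.321 with an estimated correlation, and had medians of -0.05 and -0.03 on the deposited scale. In YJS9, 1134 genes were higher and 1254 lower, and 189 and 1224 on the deposited scale. Without replicate 1 there were 1464 genes and without replicate 2 there were 1483.

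YKH104, in which SPT3 was lower, had lower hexose transporter and higher proteasome transcripts. Hexose transporter genes fell with a median of -0.69 (9 of 20 lower, 10 adjusted over the list alone), HXT3 at -1.69 ± 0.24 (SE, n = 2) and HXT1 at -1.51 ± 0.14 (SE, n = 2). Proteasome genes rose with a median of 0.60 (21 of 36 higher, 27 adjusted over the list alone), PRE6 at 0.91 ± 0.14 (SE, n = 2). Phosphate response genes fell with a median of -0.23 (4 of 15 lower, 5 adjusted over the list alone), including PHM8 (-1.64) and PHO5, the repressible acid phosphatase (-1.05). Mitochondrial ribosome genes rose with a median of 0.35 (14 of 55 higher, 18 adjusted over the list alone), MRPL33 at 0.74. Without replicate 1, HXT3 (-1.70), PHO5 (-0.95), PRE6 (0.74) and MRPL33 (0.63) no longer passed, nor did MRPL33 without replicate 2 (0.85).

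SSA3 was higher in YKH104 by 3.11 ± 0.24 (SE, n = 2), HSP26, a small heat shock protein gene, by 1.82 ± 0.28 (SE, n = 2) and SIP18 by 1.49 ± 0.29 (SE, n = 2). SER3 of serine synthesis was at 2.67 and 2.5 on the 2 arrays. RNR3, a DNA-damage-inducible ribonucleotide reductase subunit, was lower by -2.29 ± 0.35 (SE, n = 2), HTC1 by -2.15 ± 0.26 (SE, n = 2) and YNL040W by -2.12 ± 0.14 (SE, n = 2). Without replicate 1, RNR3 was at -1.33 and did not pass, nor did HSP26 (1.38), SIP18 (1.60) or CWP1 (-1.82), of which SIP18 (1.39) and CWP1 (-1.51) did not pass without replicate 2 either. UBP2, a ubiquitin protease (0.01 and 5.01), and KKQ8 (-4.95 and -0.02) each rested on 1 array, and fell to 0.16 without replicate 2 and -0.12 without replicate 1, where neither passed. Heat shock proteins had a median of 0.50 (9 of 26 higher, 11 adjusted over the list alone; adjusted p = 0.061 with an estimated correlation). Seripauperin genes had a median of -0.74 (6 of 25 lower, 14 adjusted over the list alone; adjusted p = 0.205 with an estimated correlation) and cell wall genes of -0.46 (8 of 27 lower, 12 adjusted over the list alone; adjusted p = 0.0812 with an estimated correlation), CWP1 at -1.67. The SAGA list had a median of 0.00 and a mean of -0.55, with SPT3 as its 1 lower member (1 adjusted over the list alone; adjusted p = 0.014, or adjusted p = 0.175 with an estimated correlation). Ribosomal protein genes (-0.33, 20 of 134 lower and 1 higher, 23 and 1 adjusted over the list alone) and respiration genes (0.31, 6 of 34 higher, 7 adjusted over the list alone) had adjusted p = 0.291 and 0.215 with an estimated correlation. In YKH104, 356 genes were higher and 390 lower, and 2 and 6 on the deposited scale. Without replicate 1 there were 72 genes and without replicate 2 there were 106.

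YKH106 had few changed genes, which overlapped with those of YKH104. SIP18 was higher by 2.99 ± 0.29 (SE, n = 2), SSA3 by 1.95 ± 0.24 (SE, n = 2), GIS1, a transcription factor of nutrient limitation, by 1.66 ± 0.31 (SE, n = 2), MSS4, a phosphoinositide kinase, by 2.77 and ASK10 by 1.35. MSS4 was at 1.38 without replicate 1, where it did not pass, and at 4.16 without replicate 2. PDR12, a weak-acid transporter, was lower by -1.81 ± 0.26 (SE, n = 2), FIG1 by -1.46 ± 0.19 (SE, n = 2), RCK1, a protein kinase, by -1.66, BDH2 by -1.36 and TDA6 by -1.22. General stress genes rose with a median of 0.33 (6 of 36 higher, 10 adjusted over the list alone), RTN2 at 1.20 and PGM2, a phosphoglucomutase, at 1.14. Mitochondrial ribosome genes had a median of 0.21 and passed camera (adjusted p = 0.0495 with an estimated correlation), although none of its 55 members passed alone. Seripauperin genes had a median of -0.37 (adjusted p = 0.215 with an estimated correlation) and hexose transporters of -0.24 (1 of 20 lower, 1 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation). Lists with small medians that passed with the preset correlation were proteasome (0.27), respiration (0.20), TCA cycle (0.23), sulfur (0.16), heat shock (0.11), amino acid biosynthesis (0.10), mating (-0.24), cell wall (-0.18) and glycolysis genes (-0.18). With an estimated correlation their adjusted p-values were 0.134, 0.187, 0.0518, 0.291, 0.375, 0.548, 0.0852, 0.157 and 0.405. Hexose transporter, mating, cell wall and glycolysis genes had medians of -0.07, -0.07, -0.01 and -0.01 on the deposited scale. COS genes, a subtelomeric family, had a median of -0.12, which was 0.05 on the deposited scale (adjusted p = 0.423 with an estimated correlation). SIP18 was the only gene named here for YKH106 that passed with either array left out, although apart from MSS4 their values moved by less than 1.5 times. In YKH106, 35 genes were higher and 25 lower, and 1 and 0 on the deposited scale. Without replicate 1 there were 20 genes and without replicate 2 there were 12.

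YKH107, the other strain with low SPT3, had the lowest hexose transporter median of the 11 groups. These genes fell with a median of -1.08 (16 of 19 lower and 1 higher, 16 and 1 adjusted over the list alone), HXT4 at -3.11 ± 0.61 (SE, n = 2) and HXT1 at -2.64 ± 0.14 (SE, n = 2). Genes of G1 and S phase fell with a median of -1.13 (16 of 25 lower and 1 higher, 16 and 1 adjusted over the list alone), including RNR1, the large ribonucleotide reductase subunit (-2.95), and the G1 cyclin CLN2 (-2.90). Sulfur and methionine genes rose with a median of 1.01, which was 0.05 on the deposited scale (12 of 22 higher and 1 lower, 15 and 1 adjusted over the list alone), MUP3, a methionine permease, at 1.80. SSA3 rose by 4.54 ± 0.24 (SE, n = 2), MFA1, an a-factor gene, by 4.28 ± 0.65 (SE, n = 2), HSP26 by 4.19 ± 0.28 (SE, n = 2), ARN1, a siderophore transporter, by 3.54 ± 0.16 (SE, n = 2) and SLH1 by 3.34 ± 0.21 (SE, n = 2). CWP1, a cell wall mannoprotein, was lower, at -3.38, as were OLE1 (-3.15) and ARO5 (-3.14).

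TFIID subunit genes in YKH107 had a median of 0.44 (4 of 9 higher, 5 adjusted over the list alone; adjusted p = 0.0852 with an estimated correlation) and a median of -0.52 on the deposited scale, with TAF11 at 1.43 and TAF3 at 1.06. Mitochondrial ribosome genes (0.60, 37 of 55 higher, 40 adjusted over the list alone; adjusted p = 0.0619 with an estimated correlation), proteasome genes (0.78, 25 of 36 higher, 25 adjusted over the list alone; adjusted p = 0.123 with an estimated correlation) and iron genes (0.66, 11 of 21 higher and 1 lower, 11 and 1 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation) had medians below 0 on the deposited scale. Heat shock proteins (0.93, 19 of 26 higher, 19 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation) had a median of -0.03 there. Ribosomal protein genes had a median of -0.73 (88 of 135 lower and 5 higher, 90 and 6 adjusted over the list alone; adjusted p = 0.246 with an estimated correlation). Ergosterol genes had a median of -0.47 (11 of 23 lower and 3 higher, 11 and 3 adjusted over the list alone; adjusted p = 0.375 with an estimated correlation), ERG26 at -1.80. Cell wall genes (-0.41, 11 of 26 lower and 4 higher, 12 and 4 adjusted over the list alone) had adjusted p = 0.23 with an estimated correlation. General stress (0.50) and respiration genes (0.33) had adjusted p = 0.311 and 0.47 with an estimated correlation, and medians of -0.46 and -0.63 on the deposited scale. In YKH107, 1294 genes were higher and 1368 lower, and 31 and 2940 on the deposited scale. Without replicate 1 there were 1628 genes and without replicate 2 there were 1493.

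YKH108 raised stress and TCA cycle genes and lowered ribosomal protein genes. General stress genes rose with a median of 1.26 (30 of 36 higher, 33 adjusted over the list alone), DDR2 at 2.30 ± 0.45 (SE, n = 2) and RTN2 at 2.12 ± 0.16 (SE, n = 2). TCA cycle genes rose with a median of 1.41 (12 of 15 higher, 12 adjusted over the list alone), IDH1 at 1.84 ± 0.20 (SE, n = 2). Ribosomal protein genes fell with a median of -0.90 (109 of 135 lower, 1 higher and 112 lower adjusted over the list alone), ASC1, a ribosome-bound signalling protein, at -2.12 ± 0.24 (SE, n = 2). SLH1 was higher by 3.42 ± 0.21 (SE, n = 2), DUR3 by 2.90 ± 0.38 (SE, n = 2), SIP18 by 2.88 ± 0.29 (SE, n = 2), MEP2 by 2.41 ± 0.21 (SE, n = 2) and FET3, the iron-uptake oxidase, by 2.40 ± 0.38 (SE, n = 2). FET3 was at 1.46 without replicate 2, and DDR2 did not pass without replicate 1 (1.80).

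MF(ALPHA)2 (-2.36) and PHO3 (-2.20) were lower in YKH108. KTD1 (-10.5 and -0.24) and AAC3, an ADP/ATP carrier (-1.72 and -8.70), had arrays far apart, and KTD1 was at -0.38 without replicate 1 and no longer passed. AAC3 was at -1.78 without replicate 2. Glycolysis and fermentation genes had a median of 0.91 (15 of 17 higher and 1 lower, 15 and 1 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation), GPM1, the phosphoglycerate mutase, at 1.24. Mating genes had a median of 0.64 (16 of 29 higher and 6 lower, 17 and 6 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation) and of -0.05 on the deposited scale. Ribosome biogenesis genes had a median of -0.34 (25 of 73 lower, 25 adjusted over the list alone; adjusted p = 0.246 with an estimated correlation), NOP1, the fibrillarin, at -1.12. Seripauperin genes had a median of -0.91 (13 of 25 lower, 13 adjusted over the list alone; adjusted p = 0.47 with an estimated correlation). TBP regulators (0.34), amino acid biosynthesis (0.10), sulfur (0.29), respiration (0.23), mitochondrial ribosome (0.37) and selection marker genes (0.57) passed with the preset correlation and had medians below 0 on the deposited scale. With an estimated correlation their adjusted p-values were 0.311, 0.548, 0.141, 0.469, 0.185 and 0.108. In YKH108, 937 genes were higher and 1096 lower, and 55 and 1642 on the deposited scale. Without replicate 1 there were 1055 genes and without replicate 2 there were 1000.

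YKH109, with 3 arrays where the other groups had 2 or 1, had 2901 changed genes, and 2377 to 2660 with 1 array left out. With at least 1.5-fold it had 1840, fewer than the 2021 of YKH107. Replicate 2 of YKH109 had values for 5955 spots, the fewest of all arrays. Its values had a standard deviation of 1.16, against 0.83 in replicate 1 and 0.77 in replicate 3. It correlated at 0.507 and 0.56 with these replicates, which correlated at 0.794 with each other. SIP18 rose by a log2 of 5.81 ± 0.24 (SE, n = 3), GIS1 by 3.93 ± 0.31 (SE, n = 2), RTN2 by 3.88 ± 0.13 (SE, n = 3), SSA3 by 3.84 ± 0.20 (SE, n = 3) and GPH1, the glycogen phosphorylase, by 3.50 ± 0.19 (SE, n = 3). General stress genes rose with a median of 1.95 (30 of 36 higher and 1 lower, 30 and 1 adjusted over the list alone), and TCA cycle genes with a median of 1.16 (11 of 15 higher, 11 adjusted over the list alone), CIT1 at 2.91 and MDH1, a malate dehydrogenase, at 2.46. Sulfur and methionine genes rose with a median of 0.70 (12 of 22 higher and 2 lower, 12 and 2 adjusted over the list alone), STR3 at 3.49 ± 0.17 (SE, n = 3), although the list median was -0.15 on the deposited scale. FAA4 was lower, at -3.09, as were BNR1, a formin (-2.96), GAS3 (-2.89) and SPO16, a meiotic gene (-2.82). The arrays of SPO16 were at -2.06, -4.36 and -2.28, with replicate 2 the lowest.

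Ribosomal protein genes in YKH109 had a median of -0.80 (104 of 134 lower and 2 higher, 104 and 2 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation). Genes of G1 and S phase had a median of -0.90 (17 of 27 lower and 1 higher, 18 and 1 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation), POL1 at -2.61 ± 0.16 (SE, n = 3). Proteasome (0.53, 24 of 36 higher, 25 adjusted over the list alone; adjusted p = 0.246 with an estimated correlation), respiration (0.30, 15 of 34 higher and 2 lower, 15 and 2 adjusted over the list alone; adjusted p = 0.438 with an estimated correlation) and mitochondrial ribosome genes (0.43, 30 of 55 higher, 30 adjusted over the list alone; adjusted p = 0.175 with an estimated correlation) had medians below 0 on the deposited scale. Ribosome biogenesis genes (-0.28, 33 of 73 lower and 5 higher, 32 and 5 adjusted over the list alone) and heat shock proteins (0.80, and -0.11 on the deposited scale) had adjusted p = 0.397 and 0.223 with an estimated correlation. UNG1, a uracil-DNA glycosylase, was at -3.37 with arrays at -8.08, -0.998 and -0.547, and at -0.71 without replicate 1. In YKH109, 1377 genes were higher and 1524 lower, and 112 and 3329 on the deposited scale.

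**Figure D3:**
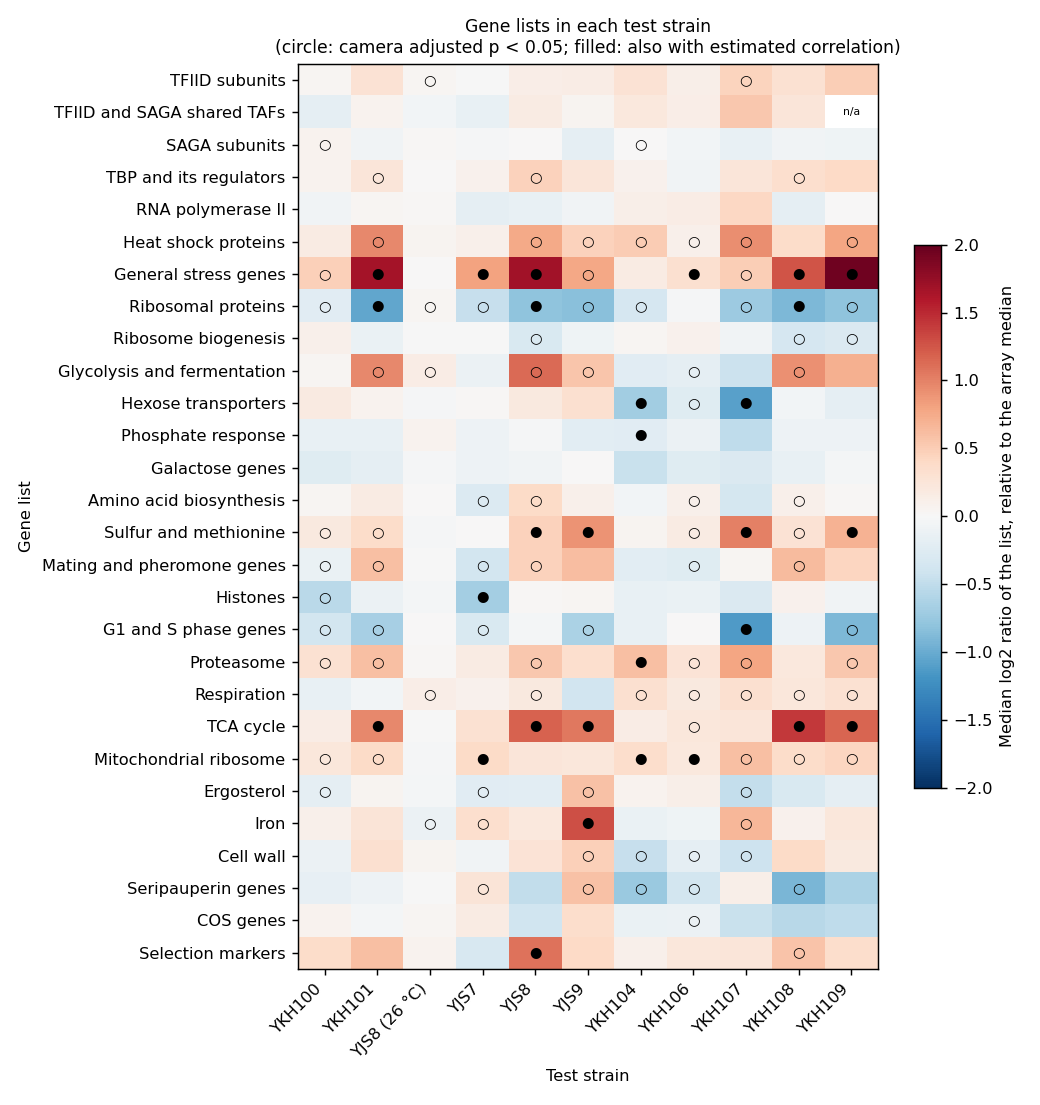
Median log2 ratio relative to the array median of each gene list (rows) in each strain (columns), with an open circle where camera passed with the preset correlation and a filled one where it also passed with an estimated one. General stress genes reach 1.95 in YKH109 and ribosomal protein genes -1.04 in YKH101, and many positive medians are negative on the deposited scale, such as mitochondrial ribosome genes in YKH107 (0.60 and -0.36).

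Over all lists, background medians in the self array pairs stayed between -0.12 and 0.06 for general stress genes, -0.06 and 0.06 for ribosomal protein genes, 0.01 and 0.14 for TCA cycle genes and -0.03 and 0.24 for hexose transporters. For heat shock proteins they ran from -0.51 to 0.07. In YJS8 at 26 °C, respiration (median 0.13), glycolysis (0.14), ribosomal protein (0.04), TFIID (0.04) and iron genes (-0.11) passed camera with the preset correlation. With an estimated correlation their adjusted p-values were 0.0628, 0.269, 0.551, 0.134 and 0.241. None of their members passed among all genes, and 1 TFIID gene passed adjusted over the list alone. All 5 medians were negative on the deposited scale, where only that of the iron genes kept its sign. Without replicate 1 camera turned the direction of the iron list (adjusted p = 0.982). The lists of RNA polymerase II and galactose genes passed in none of the 11 groups. The TAFs shared by TFIID and SAGA passed in none of the 10 groups where they were tested, and in YKH109 the 4 measured members were under the minimum of 5.

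Strains with a common reference were compared directly, which asks how far 1 strain's changes differ from another's. YKH100 and YJS8 had 1 array each, with a median standard error of the strain effect of 0.251 against 0.173 for 2 arrays. Pairs with either strain had less power, so their counts cannot be ranked against those of other pairs. YJS7 and YJS9, the strains with higher GCN5, differed in 960 genes, and YKH100 and YKH101, the strains with low GCN5, in 302. YKH104 and YKH107, the strains with low SPT3, differed in 816 genes, with 477 at a higher level in YKH104. On the deposited scale these counts were 37, 3 and 1329, with 1326 of the last at a higher level in YKH104. YKH104 and YKH106 differed in 9 genes, YKH101 and YJS8 in 47, YKH101 and YJS9 in 135, and YKH108 and YKH109 in 279, of which 197 were at a higher level in YKH108. On the deposited scale these pairs differed in 1, 5, 1 and 12 genes.

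Strain effects were correlated across genes, which are not independent replicates, over 55 pairs. The highest Pearson r was 0.81 between YKH101 and YJS9 (Spearman rho 0.81), followed by 0.78 between YKH101 and YKH108 (rho 0.78) and 0.77 between YJS8 at 37 °C and YKH108 (rho 0.79). YKH108 had another reference strain than YKH101 and YJS8. YKH104 correlated with YKH107 (r = 0.71, rho 0.69) and YKH106 (r = 0.66, rho 0.71), and YKH108 with YKH109 (r = 0.74, rho 0.76). The largest absolute r of a strain effect with a pair of self arrays was 0.214. In 100 simulations without effects the highest r was 0.11. They drew independent noise for each gene and array, so they show only what the design itself adds. They held no shared reference RNA, no array series and no spots that fail to follow the array median.

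YKH101 and YJS9 shared 703 higher and 883 lower genes, where independent lists would share 215 and 258. YJS8 and YKH108 shared 370 higher and 388 lower genes against 76.2 and 84.5, and YKH104 and YKH107 shared 290 and 318 against 83.5 and 96.9. Of the 60 genes of YKH106, 24 higher and 24 lower ones were shared with YKH104, against 2.27 and 1.78. The covariance of effects was 0.43 for YKH101 and YJS9 and 0.31 for YJS8 and YKH108. In the simulations of independent noise it was 4.73e-05 and 0.000597. The labels do not say which arrays shared a reference culture, so part of the excess between strains with a common reference may come from shared RNA.

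**Figure D4:**
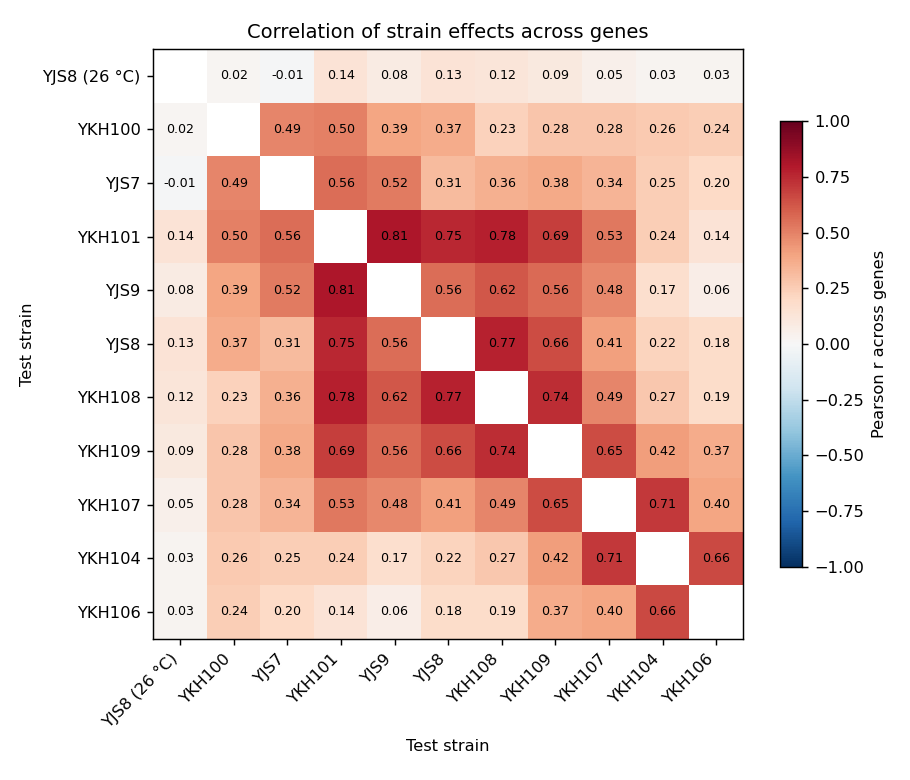
Pearson correlation across genes between the effects of each pair of strains, on values relative to the array median. Cell colours and printed numbers give r, which is highest, at 0.81, between YKH101 and YJS9 and lies between -0.01 and 0.14 for YJS8 at 26 °C.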

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

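The test of the temperature difference was planned before the data were examined, and the tests of unnamed spots, of the repeated column, of glycolytic genes and of the array medians were chosen after their results had been seen.

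The effect of strain YJS8 differed between 37 °C and 26 °C in 413 genes, by a limma contrast of the 2 effects. It set 1 array at 37 °C against 2 at 26 °C. With the repeated column kept under both strains, as the design was first written, there were 12 genes, and with it as YJS8 alone 7. Both settings enter the column as YJS8, although its GCN5 and SLH1 values lay outside those of the other YJS8 arrays, as given below. Read as YKH100 alone, the column left the number of genes within 1.5 times that reported. On the deposited scale limma called 0 genes in this contrast, with 482 at an unadjusted p under 0.05.

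Spots without a gene name in the platform table were not part of any comparison. In YKH109, 284 of 775 tested unnamed spots passed the same limma threshold, 146 higher and 138 lower. The most in a pair of self arrays was 7, but a pair combined 2 arrays where YKH109 had 3.

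GCN5 was at -6.01 relative to the array median in the column that YKH100 replicate 2 and YJS8 replicate 2 share, a column left out of the report's comparisons. On the 3 other arrays of YJS8, GCN5 ran from -0.08 to 0.51 and SLH1 from 2.85 to 3.94, and with SLH1 at 0.08 in the column both genes, 2 of 2, lay outside by more than that range, which argues against an array of YJS8 entered a second time under YKH100. An array of YKH100 entered a second time under YJS8 stays open. Among the groups GCN5 was low only in YKH100 (-4.97) and YKH101 (-5.40), where SLH1 was at 0.42 and 3.52. YPC1 and ENP1 went the other way, at 0.13 and 0.09 in the column and -6.06 and -5.25 on YKH100 replicate 1. GCN5 and SLH1 were at -4.96 and 0.40 on YKH100 replicate 1, and of 472 genes that differed by more than 1 on the log2 scale between the single arrays 87.1% lay nearer to it, but this share was 69.4% to 83.8% on the self arrays and 88.2% on YJS7 replicate 1. The column also correlated at 0.287 with YKH100 replicate 1 and at 0.576, 0.57 and 0.565 with replicate 2 of YKH101, YJS9 and YJS7. These values cannot be compared, because dye effects were not removed. The column and those replicate 2 arrays had the test strain in channel 2, and YKH100 replicate 1 in channel 1. Opposite orientations of YJS7 and of YKH106 correlated at 0.273 and 0.292. No array was moved between strains.

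Glycolysis and fermentation genes lay above the array median in YKH101, YJS8 at 37 °C, YJS9 and YKH108. YKH109, which was not part of the test below, had a list median of 0.72. There it was 0.42 among members that followed the array median, and -0.25 for the list on the deposited scale. Bright spots near the ceiling of the detector could stay near 0 while the array median falls. Members that followed the array median on the self arrays had a slope of at least 0.5 on it. Among these members the lowest list median over the 4 strains was 0.553. The whole list ran from -0.16 to 0.0911 in pairs of self arrays. This argues against the members that did not follow the median as the whole cause. A ceiling that held back the others in part was not excluded, since medians of self array pairs moved less, from -0.206 to 0.381. A level held while most other transcripts fell stays open. The highest list median on the deposited scale was 0.284, and 2 of the 4 strains lay outside the range of -0.266 to 0.236 of the self array pairs.

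The array medians were below 0 in both channel orientations in YKH101, YJS9, YKH107, YKH108 and YKH109. Their means over both orientations ran from -0.962 to -0.507, and 5 of 5 lay below the self array range of -0.206 to 0.381. YJS8 at 26 °C, with 1 called gene, also lay below it, at -0.262. Scanner gain set per array, less test RNA on the arrays and a lower mRNA content of the strains cannot be told apart, because the labels give neither gain, RNA amounts nor cell numbers.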

How the results depend on the processing

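The alternatives with the repeated column, with genes that did not follow the array median left out, with centring in blocks of spots and with small whole-number ratios left out were chosen after seeing the data, and the others before. Of 252 recomputed counts, 176 stayed within 1.5 times the reported count and 76 did not. For the latter the cause was not tested, except that leaving out an array or asking for 1.5-fold removes data or genes by construction. All 12 strain and temperature counts stayed within that limit with robust eBayes, no minimum number of arrays, genes with a value on every array, genes that did not follow the array median left out and small whole-number ratios left out.

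On the deposited scale the counts were 11 in YKH100, 25 in YJS7, 123 in YJS8 at 37 °C, 1413 in YJS9, 8 in YKH104 and 1 in YKH106. The temperature contrast had 0 genes by limma (482 at an unadjusted p under 0.05). Differing genes numbered 3 for YKH100 against YKH101, 3 against YJS7, 5 against YJS8 and 7 against YJS9. They numbered 106 for YKH101 against YJS7, 5 against YJS8 and 1 against YJS9, and 9 for YJS7 against YJS8, 37 for YJS7 against YJS9 and 12 for YJS8 against YJS9. YKH104 differed from YKH106 in 1, from YKH107 in 1329, from YKH108 in 75 and from YKH109 in 2007 genes. YKH106 differed from YKH108 in 526 and from YKH109 in 2308, YKH107 from YKH108 in 187 and from YKH109 in 81, and YKH108 from YKH109 in 12. TAF8 in YKH107 reversed to -0.0506 and UFD1 in YKH109 to -0.0319. Of 382 values of named genes, 199 kept direction and call, 181 lost the call and 2 reversed. Of 307 list tests, 284 were unchanged, 12 lost and 11 gained the call.

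Asking for at least 1.5-fold left 474 genes in YKH104 and 1840 in YKH109. Without a dye term YKH106 had 35. With a dye term per reference strain there were 131 in YKH100, 3 in YJS8 at 26 °C, 1231 in YJS7, 1172 in YKH104, 139 in YKH106 and 720 in the temperature contrast. With separate dye terms for low and high array numbers and the self arrays in the fit, YJS8 at 26 °C had 2. With the self arrays in the fit YKH100 had 141, YJS8 at 26 °C 3 and YKH106 112. With 1 reference strain at a time YKH100 had 34. Centring in blocks of 200 spots gave 152 in YKH100, 102 in YKH106 and 643 in the temperature contrast, and blocks of 400 gave 148 in YKH100 and 97 in YKH106.

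The design as first written kept the repeated column under both strains. Then YKH100 had 197 genes, YJS8 at 37 °C 469, YKH106 35 and the temperature contrast 12, and YJS8 at 26 °C had 0 by limma (34 at an unadjusted p under 0.05). YKH100 and YJS9 differed in 801 genes, YKH100 and YJS7 in 2, YKH100 and YJS8 in 0 (129 at an unadjusted p under 0.05) and YJS7 and YJS8 in 0 by limma (461 at an unadjusted p under 0.05). With the column as YKH100 alone YKH100 had 318 genes, and in both of these settings YAR061W in YKH100 reversed to 0.98. With the column as YJS8 alone there were 34 in YKH100, 364 in YJS8 at 37 °C, 23 in YKH106 and 7 in the temperature contrast, and 0 in YJS8 at 26 °C by limma (31 at an unadjusted p under 0.05). Of 382 values of named genes, 327, 375 and 321 kept direction and call in these 3 settings.

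Leaving out 1 array gave 1162 to 1254 genes in YKH101, 1 to 4 in YJS8 at 26 °C, 153 to 277 in the temperature contrast, 330 to 510 in YJS7, 1464 to 1483 in YJS9 and 72 to 106 in YKH104. It gave 12 to 20 in YKH106, 1493 to 1628 in YKH107, 1000 to 1055 in YKH108 and 2377 to 2660 in YKH109. A lone array was assumed to vary like the other groups. Without 1 replicate the iron list of YJS8 at 26 °C had medians of -0.239 to -0.0166 and the seripauperin list of YJS7 of 0.127 to 0.475, and without replicate 1 camera turned the direction of both. Of 660 gene values 536 kept direction and call, as did 467 of 529 list tests. That list total and the next one include lists that were called in neither fit. With an estimated correlation 216 of 307 list tests were unchanged in this sense, and 91 lost their call. YJS8 at 37 °C had 11 lists up and 2 down with the preset correlation, of which 5 kept the call, the most of any group. YKH100 had 4 up and 6 down, of which 0 kept it. Leaving out the only array of YKH100 or YJS8 at 37 °C was not run, nor was a split by TATA boxes. Spots with ratios of small whole numbers had standard deviations of 0.761 to 1.15 on self arrays against 0.259 to 0.433 for the others. They were read as dim from their ratios alone, and no intensity was used. Selecting spots by such ratios can itself widen their spread, so whether weakly expressed genes varied more was not tested.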

Other observations

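The sets in this part were chosen after their values had been seen, and no hypothesis was tested on them.

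SLH1 lay apart from most genes in its pattern over strains. It was at 3.52 in YKH101, 3.23 in YJS8 at 26 °C, 3.95 in YJS8 at 37 °C, 3.30 in YJS9, 3.34 in YKH107, 3.42 in YKH108 and 2.48 in YKH109. In YKH100, YJS7, YKH104 and YKH106 it was at 0.42, 0.23, 0.50 and 0.11 and did not pass. The largest absolute value on a self array was 0.233. SLH1 lies near TAF1 on chromosome VII. In the 7 groups with high SLH1, TAF1 passed in YKH101 (0.53) and YKH109 (0.57) and did not pass in YJS8 at 26 °C (0.51), YJS8 at 37 °C (0.27), YJS9 (0.16), YKH107 (0.30) and YKH108 (0.34). It was at 0.31 in YKH104, where SLH1 did not pass. Other neighbours differed among strains: YGR273C was lower in YKH107 (-1.22), YKH108 (-1.47) and YKH109 (-1.40), RTT102 was higher in YKH101 (1.03) and YJS9 (0.38) and lower in YKH109 (-1.22), HUA1 was higher in YKH108 (0.85) and YKH109 (0.55), and YTA7 passed in none of the 11 groups.

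Genes specific to a cells and to alpha cells moved apart to different degrees. The a-specific set held MFA1, MFA2, STE2, STE6, BAR1 and AGA2, and the alpha-specific set MF(ALPHA)1, MF(ALPHA)2, STE3 and SAG1. Of the a-specific genes, 5 of 6 were higher in YKH101, 5 of 5 in YJS9 and 5 of 6 in YKH107, with medians of 2.52, 2.19 and 2.25. ASG7, another a-specific gene of the mating list, was not in the set and was at 0.26, 0.14 and 0.38 in these strains. Of the alpha-specific genes, 4 of 4, 4 of 4 and 3 of 4 were lower, with medians of -1.35, -2.75 and -1.60. In YKH109, 3 of 6 a-specific genes were higher and 4 of 4 alpha-specific genes lower (medians 0.40 and -1.70), and in YJS7 2 of 6 and 2 of 4 (0.70 and -0.88). In YJS8 at 37 °C and YKH108 the a-specific genes had medians of 0.16 and 0.23, and 2 of 4 and 4 of 4 alpha-specific genes were lower (medians -1.10 and -0.93). In YKH104, 1 of 6 and 3 of 4 were higher and lower (medians 0.41 and -0.83). The medians of the a-specific and alpha-specific genes were 0.32 and -1.26 in YKH100, -0.25 and -0.70 in YKH106 and 0.03 and 0.07 in YJS8 at 26 °C, so in the last 2 they had the same sign.

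Unnamed spots passed in 141 cases in YKH101, 195 in YJS9, 255 in YKH107 and 142 in YKH108. They passed in 2 in YKH100, 11 in YJS7, 50 in YJS8 at 37 °C and 35 in YKH104. For 30 genes with several probes, 61 in all, the median correlation between probes of 1 gene was 0.487. YKH109 replicate 2 had the largest share of spots with ratios of small whole numbers, 5.32%.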
